A study of Homo sapiens with 6 samples.

How the data were processed

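Gene expression was measured in 6 libraries of cardiac spheroids made from human induced pluripotent stem cells of the IMR-90 line, 3 labelled Spaceflight and 3 labelled Ground control. Per the labels' protocols, total RNA was isolated with a column kit, 10 ng went into cDNA synthesis and amplification with the SMART-Seq v4 kit, libraries were made with Nextera XT, and paired-end reads of 100 nt were sequenced on a NovaSeq instrument. This protocol amplifies cDNA by PCR without molecular identifiers and does not mark strand, so counts are reads or read pairs and not molecules, and genes that overlap on opposite strands cannot be separated.

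The deposited values are raw counts per gene, whole numbers that were not normalized. Per the submitters' processing notes, the tools named were bcl2fastq 2.17.1.14, STAR 2.7.9a and HTSeq, with the GRCh38 build. The annotation release, the HTSeq version and the settings for strand and overlapping genes are not given in the sources used here. HTSeq commonly leaves out reads that fit several genes, so genes with near-identical copies can be undercounted. This is pointed out below for HSPA1A, HSPA1B and the metallothioneins. Other genes with close relatives, such as the myosin, actin and histone genes, were not checked for it. Gene symbols in the table have dots in place of hyphens. Symbols and gene IDs were matched to GENCODE 29 on GRCh38 for coordinates, gene types, exonic lengths and GC content. A current symbol matched 39870 genes, a symbol of GENCODE 29 matched 125, and an Ensembl gene ID matched 17007. A length was found for 97.2% of the tested genes. RGS5 sits on 2 rows of the table and was left out of its list.

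Total counts were between 17958221 and 25519621 per library. Libraries of the same group differed by more than sampling noise: the chi-square statistic per degree of freedom between replicates of the same group was between 11.1 and 18.3. The common biological coefficient of variation put the spread between libraries at 12.0%. Counting error is small beside it for abundant genes, but not for genes with few counts, such as CASQ2, PI15, ANO1 and IL1B. Intervals that cover counting error only are not given, since reads copied by PCR are not independent molecules.

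Genes were kept by edgeR's filterByExpr with its default minimum count of 10, which left 18139. Libraries were scaled by TMM, dispersions were estimated with the robust option, and the groups were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 without a block. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The standard error of a log2 fold change was taken as its size divided by the square root of F. CPM values are counts scaled by the TMM-adjusted library size, except those of MT.CO1, which were scaled by total counts. The 31 gene lists were fixed before the data were examined and tested with camera of limma 3.58.1 on the counts, with its preset correlation between genes of 0.01, adjusted over the lists, and repeated with an estimated correlation and with fry. Each list was also adjusted over the list alone. Log2 isoform ratios were made from counts with 0.5 added. Ratios and shares were compared by exact two-sided permutation tests, which cannot go below 0.1 with 3 against 3 libraries.

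The genes named in the text were set by a rule fixed before the data were examined. It took the 6 largest changes in each direction among called genes that averaged at least 5 CPM, did not overlap between groups and had a regular gene symbol. It then took the 2 members with the smallest p in each list called by camera that moved in the list's direction, the 1 member with the smallest p in each other list, and the genes of the isoform ratios. Other called list members, the genes in the added lists, FAP, TCF21 and MT.CO1 were chosen after their values were seen. Results for some single genes are not reported here.

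Each result was recomputed with RLE, upper quartile and total count scaling, without the count filter, with a minimum of 1 CPM in 3 libraries, with the replicate number as a block, with a gene length offset, with both of these, without mitochondrial genes, without each library in turn, with DESeq2 1.42.0, with limma-voom, with a stricter adjusted p of 0.01, with a fold of at least 2 and with glmTreat against a 1.5-fold change. A GC content offset and 4 further gene lists were added after seeing the data.

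The tests were checked on counts simulated from the means and sizes of these 6 libraries for the same 18139 genes. edgeR recovered 76.1% of 67 genes changed 1.5-fold, 100% of 67 changed 2-fold and 98.5% of 66 changed 4-fold, with 14 false calls in all. Of 10 simulated lists of 25 genes shifted by -0.4, camera called 10, and it called 0 of 30 unchanged lists. These lists were simulated without correlation between genes, so this check does not cover the effect of such correlation. All changed genes and list members were drawn from genes averaging at least 5 CPM. The recovery therefore does not cover genes with fewer counts, such as IL1B. A planted length trend with a slope of 0.20 was reduced to -0.00064 by the offset. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.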

Results

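RNA was sequenced from cardiac spheroids, small free-floating aggregates of cardiomyocytes made from human induced pluripotent stem cells of the IMR-90 line. The 3 Spaceflight libraries came from spheroids cultured for 8 days aboard the International Space Station, and the 3 Ground control libraries from spheroids kept on Earth in the same type of culture device. The table held raw counts for 61860 genes, of which 41277 had a count in some library. Total counts were 22849126, 17958221 and 25519621 in Ground control replicates 1 to 3, and 18295940, 24538500 and 20212758 in Spaceflight replicates 1 to 3. The labels do not state whether replicates came from separate differentiations, so the p-values measure the spread between these libraries, part of which may be technical.

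MYH6, the alpha myosin heavy chain of atrial and early heart muscle, was abundant in both groups and reached 21961 ± 1158 TMM-normalized CPM (mean ± SD, n = 3) in Ground control and 23294 ± 1163 CPM in Spaceflight. Libraries correlated at 0.984 to 0.985 within Ground control, 0.985 to 0.986 within Spaceflight and 0.980 to 0.985 between groups, across genes on the log2 CPM scale. The first principal component held 30.4% of the variance and placed all 3 Spaceflight libraries apart from all 3 Ground control libraries. Library composition also differed slightly. Long intergenic and antisense transcripts took 0.980 ± 0.017% of counts in Ground control and 1.10 ± 0.06% in Spaceflight, and pseudogenes 0.468 ± 0.008% and 0.506 ± 0.014%. The groups did not overlap in either share (exact two-sided permutation p = 0.1 for each, the smallest that 3 against 3 libraries can give, and 0.25 after Benjamini-Hochberg adjustment over 5 such measures).

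The main question was which transcripts differ between spheroids cultured in space and on the ground, with survival and metabolism named in the series title. Spaceflight spheroids had lower transcript levels of CASQ2, the calcium-binding protein of the sarcoplasmic reticulum, at 2.66 ± 0.77 CPM against 9.14 ± 1.78 CPM in Ground control (log2 fold change -1.79 ± 0.23, SE). Levels also fell for the secreted glycoproteins SPP1 (-1.55 ± 0.23) and THBS2 (-1.35 ± 0.18), the chloride channel ANO1 (-1.64 ± 0.24), the cytochrome P450 CYP1B1 (-1.44 ± 0.25) and PI15 (-1.98 ± 0.37), the last not called by limma-voom. The largest increases among genes averaging at least 5 CPM were in CYMP.AS1 (1.05 ± 0.17), the apelin receptor APLNR (1.04 ± 0.22), MEGF11 (0.98 ± 0.22), the phospholipase PLCB2 (0.94 ± 0.13), MSS51 (0.93 ± 0.15) and ADAM11 (0.84 ± 0.14). PLCB2 went from 48.2 ± 9.1 to 92.5 ± 10.6 CPM. CYMP.AS1 is named as an antisense gene, and the sources used here do not state that counting used strand, so its reads cannot be told apart from those of its partner.

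In GRCh38 coordinates from GENCODE 29, CASQ2 lies on chromosome 1 from 115700007 to 115768781, SPP1 on chromosome 4 from 87975650 to 87983426, and THBS2 on chromosome 6 from 169215780 to 169254044. ANO1 lies on chromosome 11 from 70078302 to 70189528, APLNR on chromosome 11 from 57233577 to 57237314, and PLCB2 on chromosome 15 from 40278176 to 40307935. All 6 are annotated as protein coding, and a gene's count covers its exons.

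Across all 18139 genes tested, 84 were higher and 154 lower in Spaceflight by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05. Most changes were small, with a median absolute log2 fold change of 0.60 among the 238 called genes, and 12 higher and 37 lower genes changed by a factor of at least 2. At an unadjusted p below 0.05, 2508 genes differed, where 906.95 would arise by chance. The counts rested on particular libraries: they were 44 higher and 80 lower without Ground control replicate 1, 14 and 31 without Spaceflight replicate 1, and 8 and 28 without Spaceflight replicate 3. Of 50 called genes that were recomputed, CASQ2, SPP1, THBS2, ANO1, PLCB2, TNNT2, ACTA1, COL6A3, CHAC1, THBS1 and WARS1 were called in all 18 alternative fits at the same threshold. The remaining genes kept their direction, which was largely fixed in advance, since all 238 called genes had groups that did not overlap. Each of the remaining genes lost its call in at least 1 fit, most often without Spaceflight replicate 3 (36 genes) or Spaceflight replicate 1 (34 genes). Of 32 uncalled genes that were recomputed, 17 were called in at least 1 fit. DESeq2 called MYH7, POSTN, HAND2, HSPA1A, MT1E, ATF3 and IFI6, and edgeR without Spaceflight replicate 2 called HAND2, MT.ND2, CCNB1, TPX2, HSPA1A, IFI6, MYLK and LRRN4. With the replicate number as a block, edgeR called MYH7, MYL7, POSTN, CCNB1, HSPA1A, HSPA1B, MT1E, SC5D, LAMP2, MYLK, LRRN4 and IFI6. The labels do not state that these numbers pair samples.

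The list of extracellular matrix genes was lower by camera. Of 31 tested, 29 had a negative fold change and the median was -0.38. COL6A3, a chain of type VI collagen, fell from 297.8 ± 44.8 to 187.7 ± 6.4 CPM (-0.67 ± 0.10, adjusted p = 0.0045 by edgeR). BGN, a small proteoglycan that binds collagen, fell by 0.68 ± 0.13 on the log2 scale, and LUM, a related proteoglycan, fell by 0.91 ± 0.18. The other called members were TIMP1, COL4A1, COL5A2, COL1A2 and LOXL2, with values of -0.74, -0.63, -0.44, -0.53 and -0.49. In total 0 members rose, 8 fell and 23 did not pass, and 22 were lower when adjusted over the list alone. LUM lost its call with upper quartile or total count scaling and with a GC offset. COL4A1 lost its call with the replicate number as a block. POSTN did not pass (-0.38 ± 0.10, adjusted p = 0.079 by edgeR). limma's camera test gave an adjusted p of 1.8e-20 with its preset correlation, and the adjusted p was 0.23 with an estimated correlation.

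**Figure D1:**
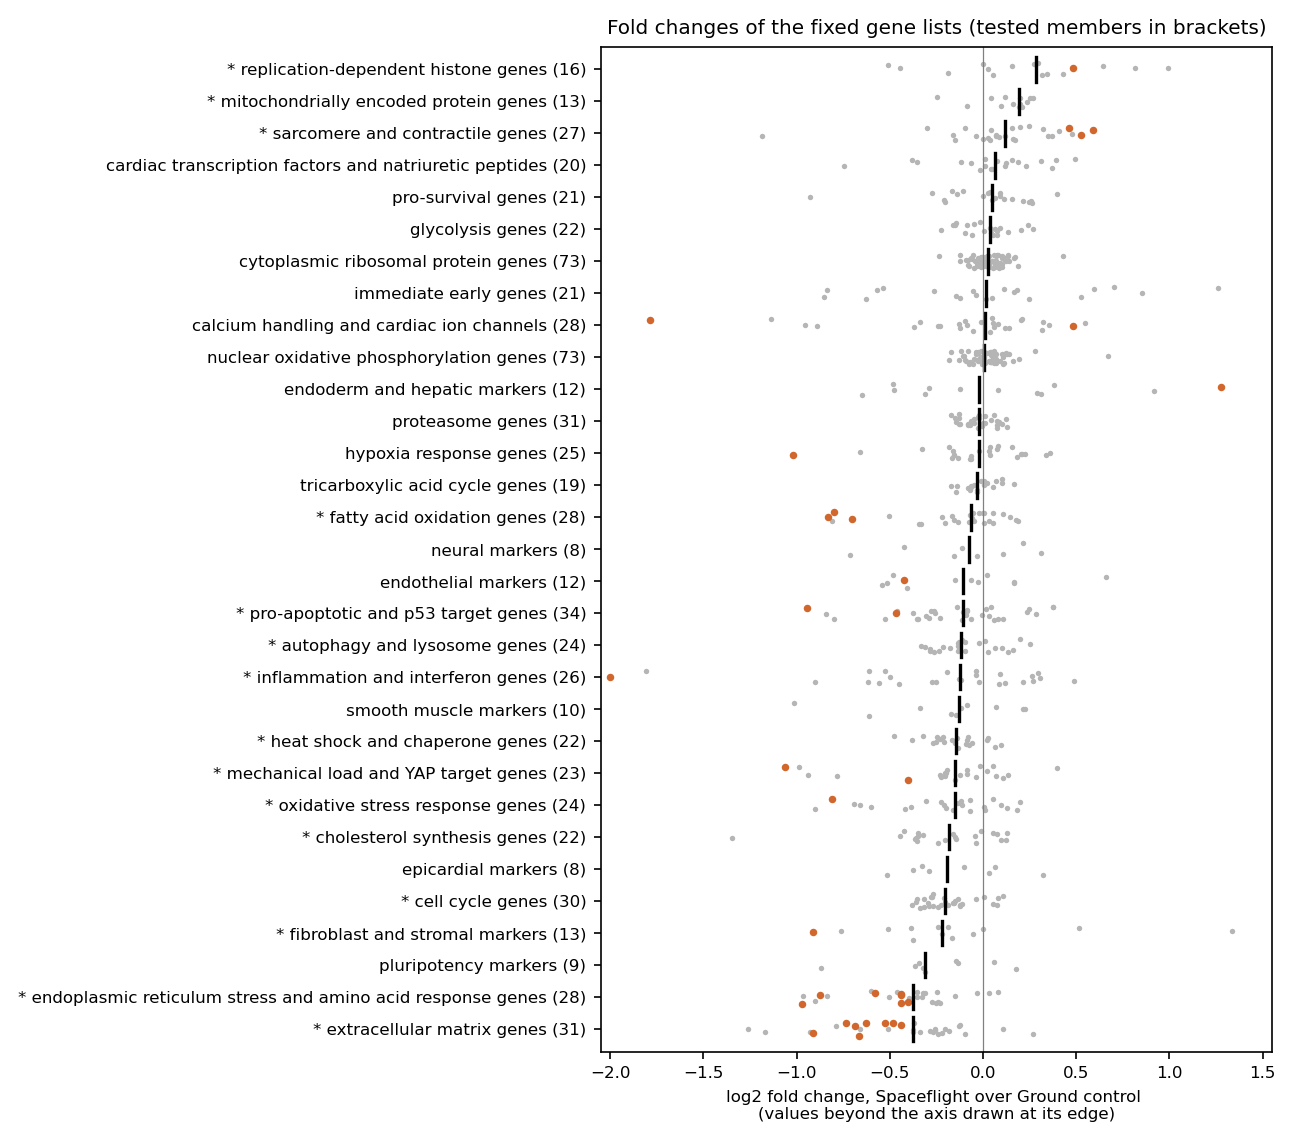
Each point is the log2 fold change (Spaceflight over Ground control, horizontal axis) of a tested member of a fixed gene list (vertical axis, number of tested members in brackets). Orange points passed edgeR's test over all genes, black bars are list medians, and stars mark lists called by camera with its preset correlation, and 1 point beyond the axis is drawn at its edge. Medians run from -0.38 for extracellular matrix genes to 0.28 for histone genes.

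The list of endoplasmic reticulum stress and amino acid response genes was also lower by camera. Of 28 tested, 26 had a negative fold change and the median was -0.38. CHAC1, which degrades glutathione, fell from 18.6 ± 2.6 to 9.46 ± 1.78 CPM (-0.97 ± 0.16, adjusted p = 0.0072 by edgeR), and MTHFD2, an enzyme of mitochondrial folate metabolism, fell from 15.2 ± 3.4 to 8.28 ± 0.82 CPM (-0.87 ± 0.17). The chaperones HSPA5 and HSP90B1 (-0.44 ± 0.09 and -0.40 ± 0.09), HERPUD1 (-0.44 ± 0.09), the serine enzyme SHMT2 (-0.44 ± 0.09) and the amino acid transporter SLC7A5 (-0.58 ± 0.12) also fell. Here 0 rose, 7 fell and 21 did not pass, and 23 were lower when adjusted over the list alone. The camera adjusted p was 6.2e-20, and the adjusted p was 0.13 with an estimated correlation, the lowest of the 31 lists by limma.

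Among survival genes, the p53 targets PMAIP1, an activator of mitochondrial apoptosis, and AEN, an apoptosis-linked nuclease, fell. PMAIP1 went from 11.4 ± 2.3 to 5.93 ± 0.50 CPM (-0.95 ± 0.18, adjusted p = 0.015 by edgeR) and AEN from 54.0 ± 4.6 to 39.0 ± 3.2 CPM (-0.47 ± 0.10, adjusted p = 0.029). Of 34 pro-apoptotic and p53 target genes, 0 rose, 2 fell and 32 did not pass, with 1 higher and 9 lower when adjusted over the list alone, a median of -0.11 and a camera adjusted p of 0.0033. The adjusted p was 0.32 with an estimated correlation (limma). No pro-survival gene passed among 21 tested, or when adjusted over the list alone. Their median was 0.05, their mean was -0.0011, and the camera adjusted p was 0.67. BCL2L2, a BCL2 relative that blocks apoptosis, had a value of 0.39 ± 0.14 (adjusted p = 0.17 by edgeR).

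In the fatty acid oxidation list 3 genes were lower in Spaceflight. PDK4, the kinase that restrains pyruvate dehydrogenase, fell from 29.1 ± 4.1 to 16.3 ± 3.6 CPM (-0.83 ± 0.15, adjusted p = 0.013 by edgeR). The mitochondrial carrier UCP3 fell from 17.6 ± 2.2 to 10.1 ± 0.8 CPM (-0.80 ± 0.14, adjusted p = 0.010). CPT1A, which brings fatty acids into mitochondria, fell by 0.70 ± 0.15 on the log2 scale and was named after its value was seen. Of 28 fatty acid oxidation genes, 0 rose, 3 fell and 25 did not pass, and 5 were lower when adjusted over the list alone. The median was -0.07, and 9 had a positive fold change. The 3 called members regulate fuel use and fatty acid entry, and none is an enzyme of the beta-oxidation spiral. The camera adjusted p was 0.0033, and the adjusted p was 0.32 with an estimated correlation (limma).

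Other parts of energy metabolism gave no called gene, also when adjusted over each list alone. The medians were 0.01 for 73 nuclear oxidative phosphorylation genes, -0.03 for 19 tricarboxylic acid cycle genes and 0.04 for 22 glycolysis genes, with camera adjusted p of 0.54, 0.74 and 0.88 (limma). The oxidative phosphorylation list was called higher without Ground control replicate 3 (0.029) or Spaceflight replicate 2 (0.027). Their members with the smallest p were NDUFA11 (0.28 ± 0.11), PDHX (-0.17 ± 0.09) and PFKM (0.24 ± 0.09), with edgeR adjusted p of 0.26, 0.43 and 0.24. The 13 mitochondrially encoded protein genes had a median of 0.19, with MT.ND2 at 0.27 ± 0.12 and MT.ND1 at 0.25 ± 0.12, and 0 passed over all genes or when adjusted over the list alone. The camera adjusted p was 0.023, and the adjusted p was 0.69 with an estimated correlation (limma). That call was lost without Ground control replicate 1 (0.12), Ground control replicate 2 (0.24), Spaceflight replicate 1 (0.089) or Spaceflight replicate 3 (0.32), and with an offset for gene length (0.25). Together these genes took 1.92 ± 0.13% of counts in Ground control and 1.99 ± 0.17% in Spaceflight, a difference of 0.07 percentage points (exact two-sided permutation p = 0.6). Scaled by total counts without TMM, MT.CO1 stood at 7101 CPM in Ground control replicate 1 and between 3874 and 4536 CPM in the other 5 libraries. This gene is part of the share above, which was not recomputed without it.

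Several contractile genes were higher. TNNT2, cardiac troponin T, rose from 1020 ± 85 to 1534 ± 66 CPM (0.59 ± 0.09, adjusted p = 0.0063 by edgeR), and LDB3, a Z-disc protein, rose from 355.7 ± 29.9 to 511.2 ± 52.2 CPM (0.52 ± 0.10). Of 27 contractile genes, 3 rose, 0 fell and 24 did not pass, with 7 higher and 1 lower when adjusted over the list alone and a median of 0.12. The camera adjusted p was 3.1e-04, and the adjusted p was 0.62 with an estimated correlation (limma). The call was lost without Ground control replicate 1 (0.063) or Spaceflight replicate 3 (0.053). Spaceflight replicate 2 was not higher, with a mean log2 level of the list at -0.09 relative to the Ground control mean, against 0.15 and 0.27 in Spaceflight replicates 1 and 3.

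MYH7, the beta myosin heavy chain of ventricular muscle, was lower in Spaceflight without passing the edgeR test, while 21 of the 27 contractile genes had a positive fold change. It stood at 591.4 ± 197.8 CPM in Ground control and 260.4 ± 44.0 CPM in Spaceflight (-1.18 ± 0.28, adjusted p = 0.15 by edgeR). DESeq2 called it (adjusted p = 0.0092), and so did edgeR without Ground control replicate 1 (0.0010). The fits with the replicate number as a block, with or without a length offset, called MYH7 too. In all, 4 of 18 alternative fits called it. The log2 ratio of MYH7 to MYH6 was -5.27 ± 0.56 (SD, n = 3) in Ground control and -6.50 ± 0.23 in Spaceflight, and the groups did not overlap (difference -1.23, exact two-sided permutation p = 0.1, adjusted 0.3). The ratio of MYL2 to MYL7, ventricular to atrial light chain, differed by -0.08, and that of TNNI3 to TNNI1, adult to fetal troponin I, by -0.18 (exact permutation p = 0.6 for each). MYH6, MYL2, MYL7, TNNI1 and TNNI3 had log2 fold changes of 0.09, 0.24, 0.35, 0.04 and -0.15, and edgeR's main fit called none of them. MYL7 was called in 3 of 18 alternative fits. These were the fit without the count filter (adjusted p = 0.0040) and those with the replicate block, with or without a length offset.

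**Figure D2:**
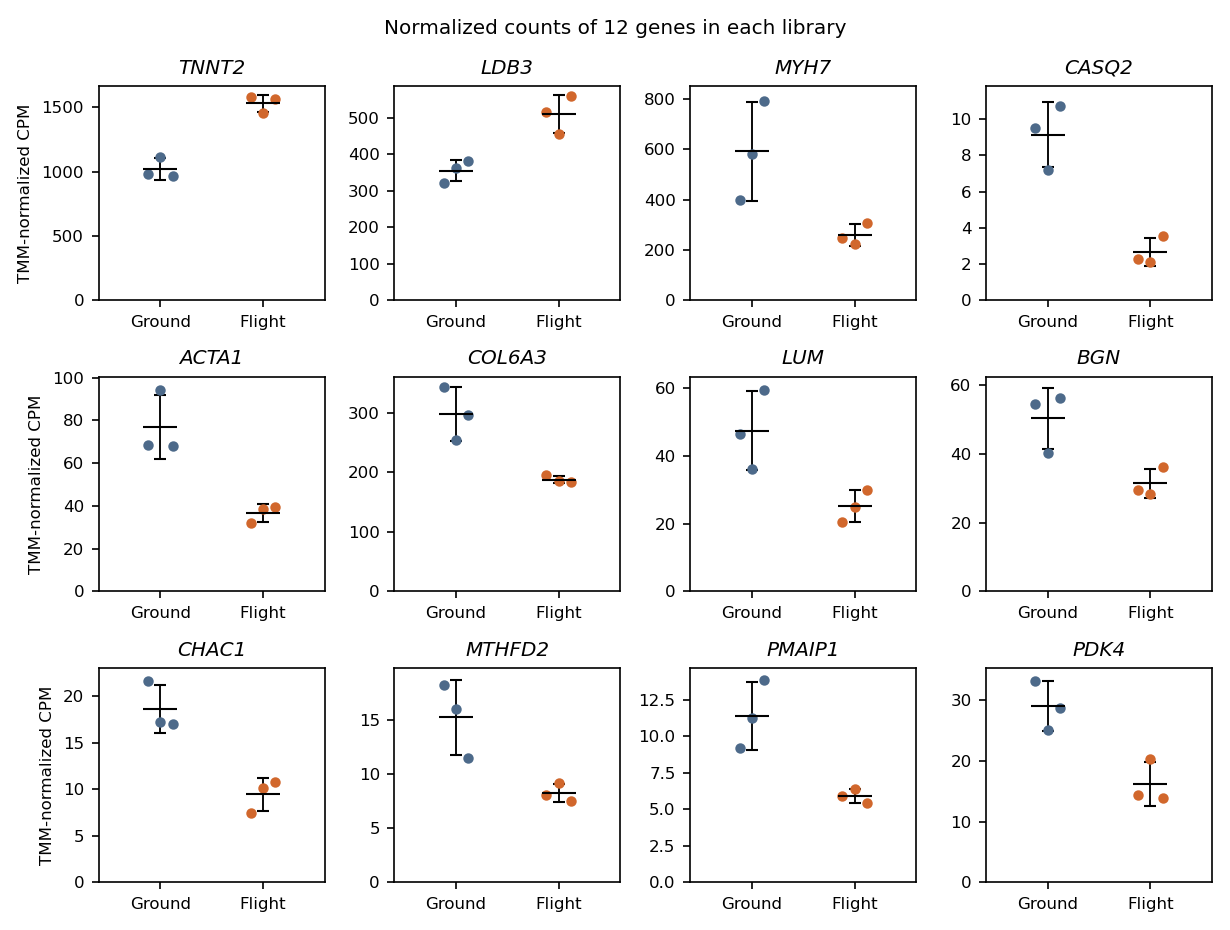
TMM-normalized CPM (vertical axes, starting at 0) of 12 genes in each of the 3 Ground control and 3 Spaceflight libraries. Points are libraries, long bars are group means and error bars are SD. TNNT2 and LDB3 lie higher in all 3 Spaceflight libraries and the other 10 genes lie lower, although MYH7 did not pass edgeR's test over all genes.

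Calcium handling and ion channel genes went both ways. CASQ2 fell as given above, while CACNA1G, a T-type calcium channel named after its value was seen, rose by 0.48 ± 0.11 (adjusted p = 0.041 by edgeR, a call lost with a length or GC offset). Of 28 genes, 1 rose, 1 fell and 26 did not pass, with 4 higher and 5 lower when adjusted over the list alone. The median was 0.01, the mean -0.12 and the camera direction lower, with an adjusted p of 0.63 (limma). Cardiac transcription factors and natriuretic peptides had a median of 0.06 over 20 genes and 0 calls, with 3 higher and 1 lower when adjusted over the list alone and a camera adjusted p of 0.057. They were called higher without Ground control replicate 3 (0.036) or Spaceflight replicate 2 (0.031), with upper quartile or total count scaling (0.049 and 0.050) and without the count filter (0.0055). HAND2 was their lead member (0.49 ± 0.14, adjusted p = 0.11 by edgeR).

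ACTA1, the skeletal alpha actin expressed in developing and loaded heart muscle, fell from 76.8 ± 15.0 to 36.7 ± 4.1 CPM (-1.06 ± 0.13, adjusted p = 0.0012 by edgeR). ITGB1, a receptor subunit that ties cells to the matrix, fell from 449.7 ± 20.7 to 340.0 ± 27.3 CPM (-0.40 ± 0.09, adjusted p = 0.031). Of 23 mechanical load and YAP target genes, 0 rose, 2 fell and 21 did not pass, with 1 higher and 2 lower when adjusted over the list alone and a median of -0.15. The camera adjusted p was 0.0071, and the adjusted p was 0.32 with an estimated correlation (limma). The call was lost without Spaceflight replicate 2 (0.082).

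Further stress lists were lower with few called genes. MT2A, a metallothionein, fell by 0.81 ± 0.18 (adjusted p = 0.046 by edgeR, a call lost with upper quartile or total count scaling and with a filter of 1 CPM in 3 libraries), and MT1E stood at -0.69 ± 0.20 (adjusted p = 0.10). Metallothioneins are close paralogs, so reads may be split among them. Of 24 oxidative stress genes 0 rose, 1 fell and 23 did not pass, with 5 lower when adjusted over the list alone, a median of -0.15 and a camera adjusted p of 0.0011. The adjusted p was 0.23 with an estimated correlation (limma). Of 22 heat shock genes 0 passed and 1 was lower when adjusted over the list alone, with a median of -0.14, a camera adjusted p of 4.8e-04, and an adjusted p of 0.23 with an estimated correlation (limma). Their lead members HSPA1A (-0.48 ± 0.13) and HSPA1B (-0.38 ± 0.13) are near-identical copies whose separate values are uncertain.

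The 30 cell cycle genes had a median of -0.21, and 25 were negative. Relative to the Ground control mean, their mean log2 level was -0.36, 0.03 and -0.23 in Spaceflight replicates 1 to 3 and 0.09, -0.08 and -0.01 in Ground control replicates 1 to 3, so Spaceflight replicate 2 was not lower. CCNB1, a mitotic cyclin, stood at -0.38 ± 0.11 and TPX2, a spindle factor, at -0.36 ± 0.12, with edgeR adjusted p of 0.094 and 0.18. No member passed, also when adjusted over the list alone. The camera adjusted p was 2.3e-04, and the adjusted p was 0.60 with an estimated correlation (limma). The 16 tested of 25 replication-dependent histone genes had a median of 0.28. Whether the cDNA protocol captured transcripts of these genes evenly was not tested, so their counts need not follow the total transcript level. H2AC6 rose by 0.48 ± 0.10 (adjusted p = 0.029 by edgeR), while H2BC5 stood at 0.43 ± 0.15 (adjusted p = 0.20). In this list 1 rose, 0 fell and 15 did not pass, with 1 higher when adjusted over the list alone and a camera adjusted p of 0.018. The adjusted p was 0.23 with an estimated correlation (limma). The histone call was lost with a gene length offset (0.10) and without Ground control replicate 2 (0.095), Ground control replicate 3 (0.097), Spaceflight replicate 2 (0.14) or Spaceflight replicate 3 (0.053).

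IL1B, an inflammatory cytokine, was detected at low level, with 37, 12 and 64 counts in Ground control and 0, 8 and 1 in Spaceflight replicates 1 to 3 (-3.51 ± 0.72, adjusted p = 0.028 by edgeR, not called by DESeq2). IFI6, an interferon-induced gene, stood at -0.50 ± 0.13 (adjusted p = 0.059). Of 26 inflammation and interferon genes 0 rose, 1 fell and 25 did not pass, with 5 lower when adjusted over the list alone, a median of -0.12 and a camera adjusted p of 0.016. The adjusted p was 0.23 with an estimated correlation (limma) and 0.14 with a filter of 1 CPM in 3 libraries. In the cholesterol synthesis list SC5D (-0.35 ± 0.10) and FDPS (-0.37 ± 0.13) led 22 genes, of which 0 passed, also when adjusted over the list alone. Its median was -0.18 and its camera adjusted p 0.012, while the adjusted p was 0.69 with an estimated correlation (limma), 0.37 without Ground control replicate 1 and 0.070 without Spaceflight replicate 1. In the autophagy and lysosome list CTSD (-0.33 ± 0.10) and LAMP2 (-0.28 ± 0.09) led 24 genes, of which 0 passed and 4 were lower when adjusted over the list alone. Its median was -0.12 and its camera adjusted p 0.039. The adjusted p was 0.36 with an estimated correlation (limma), 0.21 without Ground control replicate 1, 0.084 without Spaceflight replicate 2, 0.056 without Spaceflight replicate 3, 0.062 with a gene length offset and 0.051 with the filter of 1 CPM in 3 libraries.

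Markers of other cell types were also compared, because spheroids can hold more than cardiomyocytes. Of 13 fibroblast and stromal markers 10 had a negative fold change, and 5 of the 13 are also in the matrix list. LUM fell from 47.4 ± 11.7 to 25.2 ± 4.7 CPM, and TCF21 stood at 1.34 ± 0.41 in the opposite direction without passing. In that list 0 rose, 1 fell and 12 did not pass, with 2 higher and 5 lower when adjusted over the list alone, a median of -0.22 and a camera adjusted p of 0.0061. The adjusted p was 0.36 with an estimated correlation (limma), and 0.068 without Ground control replicate 3. EGFL7, an endothelial secreted protein, fell by 0.43 ± 0.10 (adjusted p = 0.040 by edgeR), the single call among 12 endothelial markers (2 lower when adjusted over the list alone, median -0.11, camera adjusted p = 0.11). That list was called lower without Ground control replicate 1 (0.011) or Spaceflight replicate 1 (0.015). FGB, a fibrinogen chain of liver, rose from 2.30 ± 0.55 to 5.58 ± 1.12 CPM (1.28 ± 0.25, adjusted p = 0.018), the single call among 12 endoderm and hepatic markers, also when adjusted over the list alone. That list's median was -0.02 while its mean was 0.08 and camera's direction was higher (adjusted p = 0.88).

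No gene passed among smooth muscle markers (10 tested, median -0.13, lead member MYLK at -0.61 ± 0.19), epicardial markers (8, -0.19, LRRN4 at -0.38 ± 0.11), pluripotency markers (9, -0.31, NANOG at -0.87 ± 0.35) or neural markers (8, -0.07, MAP2 at -0.71 ± 0.24). Their camera adjusted p were 0.087, 0.54, 0.25 and 0.67 (limma). Smooth muscle markers were called lower in 5 of 19 alternatives. These included the fits without Spaceflight replicate 3 (0.039), with a GC offset (0.032), with the replicate number as a block (0.0095) and without the count filter (0.042). Pluripotency markers were called lower without that filter (0.017). Adjusted over the list alone, 1 epicardial marker was higher and 1 lower, and none passed in the other 3 lists. CA12, a carbonic anhydrase, fell by 1.02 ± 0.17 (adjusted p = 0.011 by edgeR) as the single call among 25 hypoxia response genes, with 3 lower when adjusted over the list alone, a median of -0.02 and a camera adjusted p of 0.28. That list was called lower without Ground control replicate 3 (0.014) or Spaceflight replicate 1 (0.0024). No gene passed, also when adjusted over the list alone, among 73 ribosomal protein genes (median 0.03, RPLP1 at 0.17 ± 0.08), 31 proteasome genes (-0.02, PSMA5 at -0.17 ± 0.09) or 21 immediate early genes (0.02, ATF3 at -0.84 ± 0.27). Ribosomal protein genes were called higher without Spaceflight replicate 2 (0.049) and immediate early genes lower without Spaceflight replicate 3 (0.017). Their camera adjusted p were 0.28, 0.57 and 0.69 for the 3 lists in turn, and the immediate early list had a positive median and mean but a lower camera direction.

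With an estimated correlation in place of camera's preset value of 0.01, limma called 0 of the 31 lists, and 6 had an unadjusted p below 0.05. The fry test, which asks whether a list's genes move on balance in the same direction, also called 0 higher and 0 lower after adjustment, with 9 lists at an unadjusted p below 0.05. Its test for changes in either direction called 20 lists, which shows that members changed but not that they moved one way. Each of the 15 list calls above therefore holds for the preset correlation and not for the estimated value. Mean levels per library overlapped between the groups for the contractile, mitochondrially encoded, cell cycle, cholesterol synthesis, mechanical load, stromal and histone lists, and did not overlap for the other called lists.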

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

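The GC offset was chosen after the data were seen, and the other alternatives before. Scaling by RLE, upper quartile or total counts shifted the median of all genes by at most 0.014 (log2). All 50 called genes among the 82 recomputed kept their sign in every alternative, and 11 were called in each of the 18 alternative fits. Leaving out a library could hardly reverse a sign, because all 238 called genes had groups that did not overlap. The kept signs are therefore not evidence of robustness. Without Spaceflight replicate 3, 36 of the 50 lost their call, and without Spaceflight replicate 1, 34 did. The counts of 84 higher and 154 lower genes became 247 and 443 without the count filter, 188 and 327 with DESeq2, 10 and 27 at an adjusted p of 0.01, and 12 and 37 at a fold of at least 2. They were 0 and 3 with glmTreat of edgeR against a 1.5-fold change, where 108 and 207 genes had an unadjusted p below 0.05. Leaving out a library gave 8 to 95 higher and 28 to 225 lower genes, with fewer samples in the fit. The cause of the other changes was not tested.

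The numbers 1 to 3 in the labels are not stated to pair samples. Deviations from the group means correlated at 0.07, 0.05 and 0.11 between same-numbered libraries. Each library correlated best with its own number, and the second principal component, with 20.1% of the variance, placed replicates 1 at 26.4 and 21.6, replicates 2 at 0.09 and -2.43 and replicates 3 at -25.6 and -20.0 in Ground control and Spaceflight. This is a hint from the data, not the design. With the replicate block 288 genes were higher and 417 lower, and with the block and a length offset 294 and 420. camera called 3 lists higher and 13 lower with the block.

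Of the 3 lists higher and 12 lower, 0 and 0 were called with an estimated correlation and 0 and 0 with fry. The length offset left 1 list higher, alone or with the block, and leaving out a library gave 0 to 5. The difference in the mitochondrial share ranged from -0.016 to 0.16 percentage points without each library, that of MYL2 over MYL7 from -0.18 to 0.014 and that of TNNI3 over TNNI1 from -0.36 to 0.029 (log2), so these changed sign. Depth limits IL1B and other genes with few counts per library.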

Other observations

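The tests of cell composition, of the tRNA synthetase genes and of the added gene lists were chosen after the results were seen. Of 16 genes known to respond to TGF-beta, 11 had a negative fold change, 0 rose and 4 fell, and the median was -0.50. THBS1, a matrix glycoprotein that activates TGF-beta, fell by 0.72 ± 0.09 (adjusted p = 0.0012 by edgeR). PMEPA1, a feedback inhibitor of the pathway, fell by 0.80 ± 0.15, LTBP2 by 0.89 ± 0.15 and INHBA, an activin subunit, by 0.93 ± 0.17. TGFBI (-1.26 ± 0.36), which is also in the matrix list, did not pass. SMAD6 and SMAD7, inhibitors that are listed here as response genes, went the other way at 0.36 ± 0.12 and 0.24 ± 0.14 without passing. Against all other genes, limma's camera test with an estimated correlation gave the list an unadjusted p of 0.057. The list holds 4 genes of the fixed lists.

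The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 238 genes, and the highest of the others called 1, so only the real split itself gave as many. In a split that mixes the groups, a real group difference adds to the spread within each side. Few gene calls there are therefore weak evidence. The real split called 15 lists with camera's preset correlation, but other splits called between 4 and 13, and again only the real split gave as many. Many lists therefore pass with that setting in splits that mix the groups. Of the 15 called lists, 7 had their lowest p in the real split: extracellular matrix, endoplasmic reticulum stress, heat shock, oxidative stress, fatty acid oxidation, autophagy, and inflammation genes. The extracellular matrix and endoplasmic reticulum stress lists were each called in 6 of the 9 other splits. Heat shock, oxidative stress and fatty acid oxidation genes were each called in 2 of them, and autophagy and inflammation genes in 0. Each other split holds unequal shares of both groups on its 2 sides, so part of a real difference carries over. Calls there do not by themselves speak against a list, nor does their absence speak for it. The direction of those calls was not compared. Counting the real split itself, 4 of the 10 splits gave contractile genes a p as low as the real one. The number was 3 for cell cycle genes, 4 for stromal markers, 6 for mitochondrially encoded genes and 7 for cholesterol synthesis genes. For histone, pro-apoptotic and mechanical load genes it was 2 each.

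A first pattern to follow up is the lower level of extracellular matrix genes. A trend with gene length or GC content is argued against as the whole cause, since the median of -0.38 became -0.37 after a length offset and -0.36 after a GC offset. A smaller share of stromal cells is a candidate explanation. If it were the whole cause, stromal markers outside the matrix list would move alike, but the 8 such markers differed by more than their errors (Cochran's Q = 41.6 with 7 degrees of freedom), from -0.76 for FAP to 1.34 for TCF21. Their median was -0.11 and their weighted mean -0.07, against the matrix median of -0.38. This test takes each marker to be made mainly by stromal cells and the genes to be independent, and a partial contribution of cell composition stays open, as does a response of the cells to flight.

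A second pattern is the lower level of stress and amino acid response genes. Length and GC offsets left the median of -0.38 at -0.37 and -0.37, which argues against those trends. Lower activity of ATF4, the transcription factor of the amino acid response, is a hypothesis that makes a prediction outside the list: synthetases known as ATF4 targets should be lower than other cytosolic synthetases. The 12 targets had a mean log2 fold change of -0.27 ± 0.16 (SD) and the 8 others -0.04 ± 0.09, with an exact permutation p of 0.0015 over gene labels. Of the 12 targets 2 were called, and against all other genes limma's camera test with an estimated correlation gave the targets an unadjusted p of 0.065. Genes are not independent replicates, so this may overstate the evidence, and whether flight, medium supply or handling lowered such activity was not tested. The synthetase comparison bears on the amino acid response genes of the list. It does not address the chaperones in it, such as HSPA5 and HSP90B1.

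The last pattern is the higher level of contractile genes. A length trend is argued against as the cause, since the median was 0.12 before and 0.12 after the offset. A larger share of cardiomyocytes could raise them, but as the whole cause it would move them alike. The contractile genes differed by more than their errors (Cochran's Q = 117 with 26 degrees of freedom, and 93.9 with 25 without MYH7). This test takes the genes to be independent and each to be made mainly by cardiomyocytes. It was chosen when their fold changes were already known. Relative to the Ground control mean, the mean log2 level of the list was -0.11, 0.02 and 0.09 in Ground control and 0.15, -0.09 and 0.27 in Spaceflight replicates 1 to 3. That of mitochondrially encoded genes was -0.06, -0.09 and 0.15, and 0.20, -0.09 and 0.28, and mitochondrial ribosomal RNA took 2.3, 2.1 and 2.5%, and 2.5, 2.0 and 2.8% of counts. All 3 measures were highest in Spaceflight replicates 1 and 3 and Ground control replicate 3, so a difference between libraries that moves them together stays open. Changes within cardiomyocytes and any shift in composition also stay open, and the splits given above leave this list weakly separated from the variation between libraries.

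The 6 tested of 17 myeloid marker genes had a median log2 fold change of -0.45 with a median standard error of 0.35, and 4 were negative. Of these 0 passed, and LAPTM5 (0.0036 ± 0.52) and SPI1 (0.26 ± 0.48) did not fall. The untested markers had between 0 and 31 counts over the 6 libraries together. Whether myeloid cells were present or became fewer therefore stays unsettled. Ground control replicate 1 held 3858 genes with counts in no other library, which made up 0.038% of its counts.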
